A study of Mus musculus with 9 samples.

How the data were processed

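RNA was measured by sequencing in 9 libraries from mouse male germ cells, titled spermatocytes and labelled PD 35, in 3 groups of 3: wild-type controls, ClpP conditional knockouts (cKO) and ClpX conditional knockouts. Stra8-Cre, which acts from the late spermatogonial stage, deleted the genes in germ cells. Per the labels, RNA was extracted with a column kit, 1.3 ug of total RNA went into each library, and the SMARTER mRNA-Seq kit was used. The labels name no method of cell isolation, no batch and no origin of the replicates, so p-values measure only the spread between these libraries.

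The deposited table holds FPKM, a read count relative to gene length and library size, computed by the authors for 54532 genes against GRCm38 (mm10). The aligner, the counter and their versions are not stated. The table also gives a gene length in bases per the file headers, a column of another unit than FPKM. FPKM multiplied by this length was a whole multiple of 1 step per library for 100% of values (tolerance 0.01 of a step), so reads per gene were recovered, 14334436 to 17021685 per library. The per-million denominator that these steps imply was not the library's own total of gene reads. It was 0.919 ± 0.028 times that total in the controls, 1.05 ± 0.0037 in ClpP cKO and 1.07 ± 0.017 in ClpX cKO (mean ± SD, n = 3 each). The deposited values therefore carry a factor between libraries whose origin is not stated. Gene identifiers, symbols and positions are those of the table, of which 54495 identifiers are in GENCODE mouse release 21 of the M series, 53585 with the same start and end.

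Genes with a mean FPKM of at least 1 over the 9 libraries were tested, 17266 in all, of which 12827 are protein-coding. The values log2(FPKM + 1) were fitted with limma 3.58.1 in R 4.3.3, all 9 libraries in 1 model with 6 residual degrees of freedom and a trend in the prior variance. The 3 comparisons were ClpP cKO against control, ClpX cKO against control, and ClpX cKO against ClpP cKO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, two-sided. Folds are those of FPKM + 1 unless FPKM means are given. Errors are SE of the fitted log2 change, or SD over 3 libraries for FPKM.

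The test, its alternatives, 37 gene lists and the rule for named genes were chosen before the data were examined. There were 11 lists of cell type markers and 26 lists of gene groups, and 20 genes stood in more than 1 list. List counts are of tested members only, which were 15 of 22 integrated stress response genes and 9 of 20 interferon-stimulated genes. Also tested were 4 of 8 endothelial, 4 of 6 erythroid, 526 of 948 X-linked and 9 of 183 Y-linked genes. Each list with at least 5 tested members (35 lists) was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Camera compares a list with all other tested genes, and 4439 of the tested genes were not protein-coding. Beside each count over all genes stands the count of members that passed when p-values were adjusted over the list alone. Per knockout against control, the named genes were the 8 largest increases and the 8 largest decreases among called protein-coding genes whose 3 knockout values all lay on 1 side of the 3 control values. For ClpX cKO against ClpP cKO the limit was 5 each way. In every list, up to 3 called members with the smallest adjusted p were added, and Clpp and Clpx were always named. Other genes that are named were chosen after their values were seen.

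Because both knockouts share the controls, their changes were also compared in 20 simulated sets of 9 libraries without any group difference. Each gene was drawn independently of the others in these sets. On simulated reads with the same genes and library totals, where 200 genes changed in ClpP cKO, the test recovered 45 of 100 genes changed 1.5-fold and 61 of 100 changed 2-fold. It called 4 unchanged genes there, and 0 in the ClpX cKO comparison, where nothing changed and 5.01% of genes had an unadjusted p under 0.05. In the data 44.7% and 65.6% of genes were called against control, which eases the adjusted threshold. The recovery therefore does not measure the power of those comparisons.

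Alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, fits on the 6 libraries compared, the replicate number as a block, a robust variance prior, protein-coding genes only, and leaving out each library. Chosen after seeing the data were limma voom on the recovered reads, scaling by the library's own total of gene reads, and leaving out Control 3 and ClpX cKO 1 together. Also chosen after seeing the data were 5 lists: cytosolic and mitochondrial aminoacyl-tRNA synthetases, amino acid transporters, mitochondrial rRNA and tRNA genes, and small nucleolar and nuclear RNA genes. Calculations before the fits used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots used matplotlib 3.10.9.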

Results

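Gene expression was measured by RNA sequencing in material labelled as germ cells of male mice, in 3 control, 3 ClpP cKO and 3 ClpX cKO libraries. Sertoli cell markers such as Clu and Wt1 and spermatid genes such as Tnp2 were also measured in the controls, at values given below. The changes below therefore cannot be read as changes within spermatocytes alone, and the shares of other cells in the libraries were not settled. ClpP is a protease of the mitochondrial matrix, and ClpX is the ATPase that unfolds proteins and feeds them to it. The libraries held between 14334436 and 17021685 gene reads, and both of these were controls. The comparisons address what the loss of either gene does to germ cells, to their mitochondria and to the mTORC1 pathway. On the first principal component, which held 66.5% of the variance, the control libraries lay at -55.8, -52.4 and -39.2, the ClpP cKO libraries at -3.41, 13.2 and 8.13, and the ClpX cKO libraries at 19.1, 54.7 and 55.5. Control 3 and ClpX cKO 1 stood apart from their groups towards the others.

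Both targeted genes fell in their own knockout. Clpp (ENSMUSG00000002660, chromosome 17, 56990305 to 56996188) was at 9.36, 8.46 and 9.36 FPKM in the controls, at 5.16, 6.15 and 3.69 in ClpP cKO and at 12.8, 12.5 and 14.1 in ClpX cKO. It fell by 0.77 (log2, SE 0.14, adjusted p = 0.0088) in ClpP cKO, and all 3 libraries kept Clpp reads. It rose by 0.49 (SE 0.14, adjusted p = 0.014) in ClpX cKO, a call that was lost without ClpX cKO 3, where the change was 0.44. Clpx (ENSMUSG00000015357, chromosome 9, 65294260 to 65330658) was at 59.3, 55.7 and 54.7 FPKM in the controls, at 40.3, 36.2 and 36.0 in ClpP cKO and at 15.6, 11.3 and 13.2 in ClpX cKO. It fell by 2.01 (SE 0.11, adjusted p = 1.6e-04) in ClpX cKO. It also fell by 0.58 (SE 0.11, adjusted p = 0.0088) in ClpP cKO, which was not called under quantile normalization, where the change was -0.28.

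**Figure D1:**
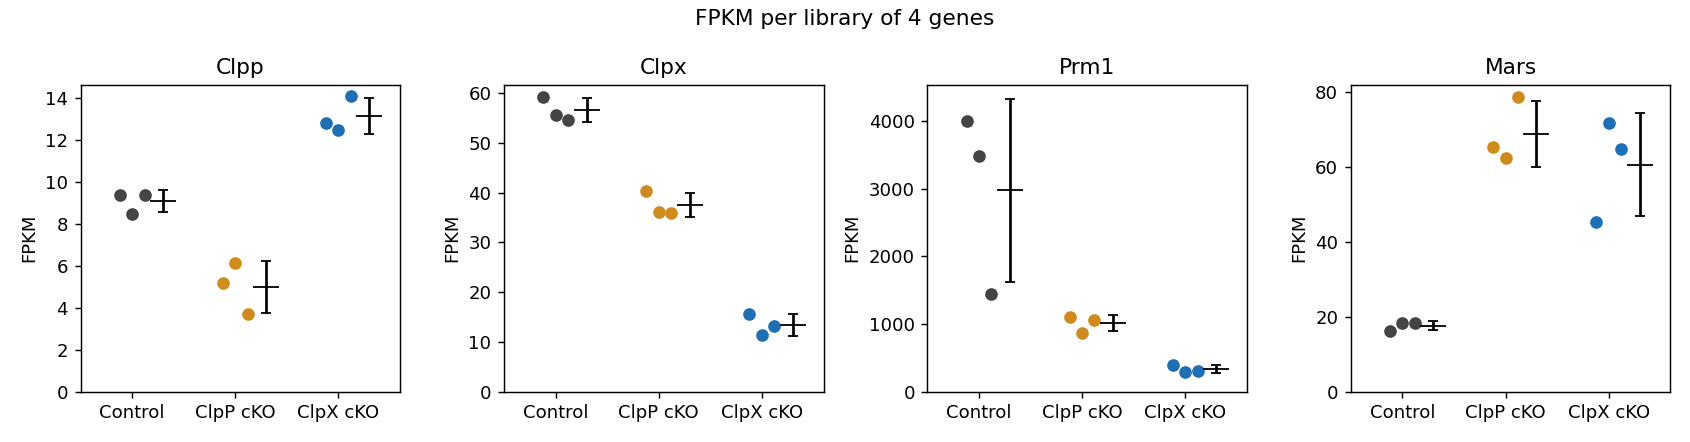
FPKM (vertical axes, starting at 0) of Clpp, Clpx, Prm1 and Mars in each control, ClpP cKO and ClpX cKO library (points), with the mean and SD of 3 libraries (bars). Clpx lies between 11.3 and 15.6 FPKM in ClpX cKO, and Prm1 varies in the controls from 1435 to 4002 FPKM.

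In ClpP cKO, Tnp1 and other genes of late spermatids fell, and several genes that charge or import amino acids, such as Mars and Slc1a4, rose. Among the largest decreases were Tnp1, a transition protein that replaces histones in spermatids (1344 ± 507 FPKM in control, 466 ± 58 in ClpP cKO; log2 change -1.45, SE 0.29, adjusted p = 0.0099), and the histone variants H2al1m (-1.49, SE 0.22) and H2al2a (-1.42, SE 0.31). Among the largest increases were Mars, the methionyl-tRNA synthetase (17.7 ± 1.18 to 68.8 ± 8.78 FPKM, 3.73-fold, adjusted p = 0.0071), Iars (2.73-fold) and Gars (2.48-fold), the isoleucyl- and glycyl-tRNA synthetases. Slc1a4, a carrier of neutral amino acids (3.59-fold), and Aldh18a1, an enzyme of proline synthesis (2.47-fold), rose as well. In all, 3573 genes rose and 4149 fell of 17266 tested, 44.7% of them, with 57 up and 380 down by at least 2-fold, and 9415 genes had an unadjusted p under 0.05. The 3 libraries of each group did not overlap for 61.7% of genes, where chance gives 10%. Of the calls, 46.3% were increases, against 58.5% under quantile normalization and 71.4% when libraries were scaled by their own totals of gene reads, which moved the median of all genes from 0.01 to 0.16 (log2). Among protein-coding genes 3306 rose and 3017 fell, and among the other 4439 tested genes 267 rose and 1132 fell. With protein-coding genes only, the share of increases was 53.9%. The total of 7722 calls dropped to 4190 without Control 1, 4888 without Control 2, 3617 without ClpP cKO 2 and 4040 without ClpP cKO 3, and was 8143 without Control 3 and ClpX cKO 1.

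Germ cell genes in ClpP cKO differed by stage. All 19 elongating spermatid genes fell (19 adjusted over the list alone; median log2 change -1.25, SD over members 0.17), and so did 14 of 16 round spermatid genes (16 adjusted over the list alone; median -0.76). Prm1, a protamine of sperm chromatin, fell by 1.43 (SE 0.35, adjusted p = 0.015), a call lost without ClpP cKO 2, where the change was -1.33. It was also at 1435 FPKM in Control 3 against 4002 and 3476 in the other controls. Of 25 flagellum and axoneme genes 16 fell (18 adjusted over the list alone), among them the radial spoke gene Rsph9 (-0.61, SE 0.10). Of 16 pachytene and diplotene genes 6 fell, 1 rose and 9 did not pass (8 down and 1 up adjusted over the list alone), with a median of -0.27, or 0.01 under quantile normalization, and the cyclin gene Ccna1 at -0.81 (SE 0.13). The list's call was lost without Control 3. By contrast 11 of 18 spermatogonial genes rose (12 adjusted over the list alone; median 0.43), such as Stra8 at 0.56 (SE 0.08) and Kit at 0.57 (SE 0.09). Of 26 early prophase genes 11 rose, 3 fell and 12 did not pass (12 up and 3 down adjusted over the list alone; median 0.20), with the recombination factor Meiob at 0.65 (SE 0.11). Camera called each of these 6 lists, early prophase not without Control 1, and none with an estimated correlation (adjusted p = 0.54 for each).

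Sertoli cell markers also rose in ClpP cKO. Of 16 Sertoli cell genes 15 rose (15 adjusted over the list alone; median 0.54), including Wt1 (9.12 ± 0.486 to 13.8 ± 0.510 FPKM) and Fshr, the receptor of follicle-stimulating hormone (1.54-fold, adjusted p = 0.0086). Of 10 immune cell genes 4 rose (5 adjusted over the list alone; median 0.35), with the antigen-presentation gene Cd74 at 2.62-fold. Of 11 peritubular and stromal genes 2 rose (0 adjusted over the list alone; median 0.29), and none of 11 Leydig cell genes passed (0 adjusted over the list alone; median 0.35, or 0.54 without Control 2, 0.20 without Control 3 and 0.067 without ClpP cKO 1). None of 9 interferon-stimulated genes passed (0 adjusted over the list alone; median 0.20). Of 4 endothelial genes (median -0.03) and 4 erythroid genes (median -0.15) none passed either. Camera called the Sertoli list (adjusted p = 0.54 with an estimated correlation) and the immune list (adjusted p = 0.54 with an estimated correlation), the latter not without ClpP cKO 1 (median 0.23). The stromal list was called without Control 3 (median 0.49) or without ClpP cKO 1, and the Leydig list without Control 2.

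Mitochondrially encoded genes rose in ClpP cKO, with 8 of 13 up and 5 not passing (8 adjusted over the list alone; median 0.55, or 0.99 under quantile normalization). The complex I genes mt-Nd2 (0.71, SE 0.10, adjusted p = 0.0086) and mt-Nd4 (0.64, SE 0.10) were among them. The share of reads from the mitochondrial chromosome was 0.896 ± 0.062% in the controls and 1.54 ± 0.076% in ClpP cKO. Genes of the same complexes in the nucleus had medians near 0. In complex I 3 rose and 5 fell of 35 (1 and 1 adjusted over the list alone; median -0.01), in complexes II and III 2 rose and 1 fell of 13 (1 and 0; median -0.01), in complex IV with cytochrome c 1 rose and 5 fell of 18 (1 and 5; median -0.10), and in ATP synthase 3 rose and 1 fell of 15 (2 and 0; median 0.02). The first 3 medians were above 0 under quantile normalization and under scaling by own totals. Among chaperones and proteases of mitochondria 5 of 16 rose and 2 fell (5 and 2 adjusted over the list alone), including the chaperonin Hspd1 (0.59, SE 0.11) and the protease Lonp1 (0.57, SE 0.09). Tfam, which packages mitochondrial DNA, fell by 0.91 (SE 0.20, adjusted p = 0.011), with controls at 28.3, 28.9 and 16.8 FPKM. Camera called the encoded genes (adjusted p = 0.54 with an estimated correlation) and not the other 5 lists. Sertoli and elongating spermatid markers moved in the same libraries (medians 0.54 and -1.25), and shares of cells were not tested as a cause of the mitochondrial changes.

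Of 15 integrated stress response genes 9 rose and 6 did not pass in ClpP cKO (10 up and 1 down adjusted over the list alone; median 0.52), among them the transcription factor Atf4 (0.52, SE 0.09) and the serine synthesis enzyme Psat1 (0.87, SE 0.15). The list's call ended with an estimated correlation (adjusted p = 0.54 with an estimated correlation). Asns, another gene of the list, chosen here after its value was seen, was at -0.44 and did not pass. Of 32 mTORC1 pathway components 11 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.20), with Lamtor3, part of the lysosomal anchor of mTORC1, at 0.68 (SE 0.09) and the kinase gene Rps6kb1 at 0.46 (SE 0.07). Mtor itself, chosen after its value was seen, was at -0.21 and did not pass. The list holds activators and inhibitors of mTORC1 alike, so its median does not measure the activity of the pathway. The mTORC1 list was called (adjusted p = 0.54 with an estimated correlation), while the 18 sterol, lipid and sugar genes that mTORC1 induces, of which 8 rose and 3 fell (8 and 3 adjusted over the list alone), were not. In the same libraries Sertoli, spermatogonial and elongating spermatid markers had medians of 0.54, 0.43 and -1.25, and whether changed shares of cells account for the stress and mTORC1 changes was not tested.

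In ClpX cKO, genes of late spermatids fell and mitochondrially encoded genes rose. Prm1 (-3.05, SE 0.35, adjusted p = 4.5e-04) and Prm2 (-3.00, SE 0.38), the protamines, and Tnp2, a transition protein (4138 ± 1452 FPKM in control, 499 ± 112 in ClpX cKO; -3.00, SE 0.28), fell to 0.121, 0.125 and 0.125 times their control values. Scara3, a scavenger receptor (3.68-fold), Pcsk1n, an inhibitor of a prohormone convertase (3.70-fold), and Tnfrsf12a, the receptor of TWEAK (3.96-fold), were among the largest increases, as were Slc1a4 (3.52-fold), Mars (3.25-fold) and the mitochondrial gene mt-Nd3 (3.28-fold). In all, 5548 genes rose and 5778 fell, 65.6% of those tested, with 318 up and 1810 down by at least 2-fold, and 11922 genes had an unadjusted p under 0.05. The libraries of the groups did not overlap for 69.8% of genes, where chance gives 10%. Of the calls, 49.0% were increases, against 57.3% under quantile normalization and 63.3% when libraries were scaled by their own totals, which moved the median of all genes from 0.00 to 0.18 (log2). Of 12827 tested protein-coding genes 5138 rose and 3912 fell, and of the other 4439 tested genes 410 rose and 1866 fell. Counts in the gene lists are to be read beside those of all protein-coding genes here too. With protein-coding genes only, the share of increases was 57.1%. The total of 11326 calls was 11449 without Control 3 and ClpX cKO 1.

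All 19 elongating spermatid genes fell in ClpX cKO (19 adjusted over the list alone; median -2.33, SD over members 0.47), as did all 16 round spermatid genes (16 adjusted over the list alone; median 0.465 times the control) and 24 of 25 flagellum genes (24 adjusted over the list alone; median -0.76). Klhl10, a spermatid ubiquitin ligase adaptor, was at -1.64 (SE 0.21) and the flagellar gene Tekt5 at -1.41 (SE 0.18). Of 16 pachytene and diplotene genes 11 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.40, or -0.01 under quantile normalization). Of 18 spermatogonial genes 15 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.66), with Kit at 0.94 (SE 0.09). Of 26 early prophase genes 10 rose and 5 fell (10 and 5 adjusted over the list alone; median 0.25), with the recombinase Dmc1 at 0.71 (SE 0.08) and M1ap at -0.83 (SE 0.13). Camera called these lists except early prophase, and none with an estimated correlation (adjusted p = 0.52 for each called list). Meiotic and mitotic division genes went both ways: of 14, 6 fell, such as the kinase gene Plk1 (-0.70, SE 0.11), and 1, Mki67, rose (0.49, SE 0.08), with the same 6 and 1 adjusted over the list alone.

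All 16 Sertoli cell genes rose in ClpX cKO (16 adjusted over the list alone; median 0.96), including Sox9 (5.55 ± 0.283 to 12.9 ± 2.13 FPKM) and the secreted chaperone gene Clu (257 ± 4.40 to 530 ± 75.9 FPKM). Of 10 immune cell genes 9 rose (9 adjusted over the list alone; median 0.77), with the complement gene C1qa at 2.08-fold. Of 11 peritubular and stromal genes 8 rose (8 adjusted over the list alone; median 0.68). Without Control 3 and ClpX cKO 1 the stromal median was 1.11. Of 11 Leydig cell genes 3 rose (0 adjusted over the list alone; median 0.65). As a list they were not called, except without Control 1, Control 2, ClpP cKO 1 or ClpX cKO 2, and their median was 0.26 without Control 3 and ClpX cKO 1. Their control libraries lay apart, at 0.27, 0.42 and -0.65. Of the endothelial genes 1 of 4 rose (1 adjusted over the list alone; median 0.16), and of the erythroid genes 1 of 4 fell (0 adjusted over the list alone; median 0.29). Interferon-stimulated genes rose in 8 of 9 cases (8 adjusted over the list alone; median 0.70), such as Ifi27 (0.80, SE 0.15). Camera called the Sertoli, immune, stromal and interferon lists (adjusted p = 0.52 for each with an estimated correlation).

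**Figure D2:**
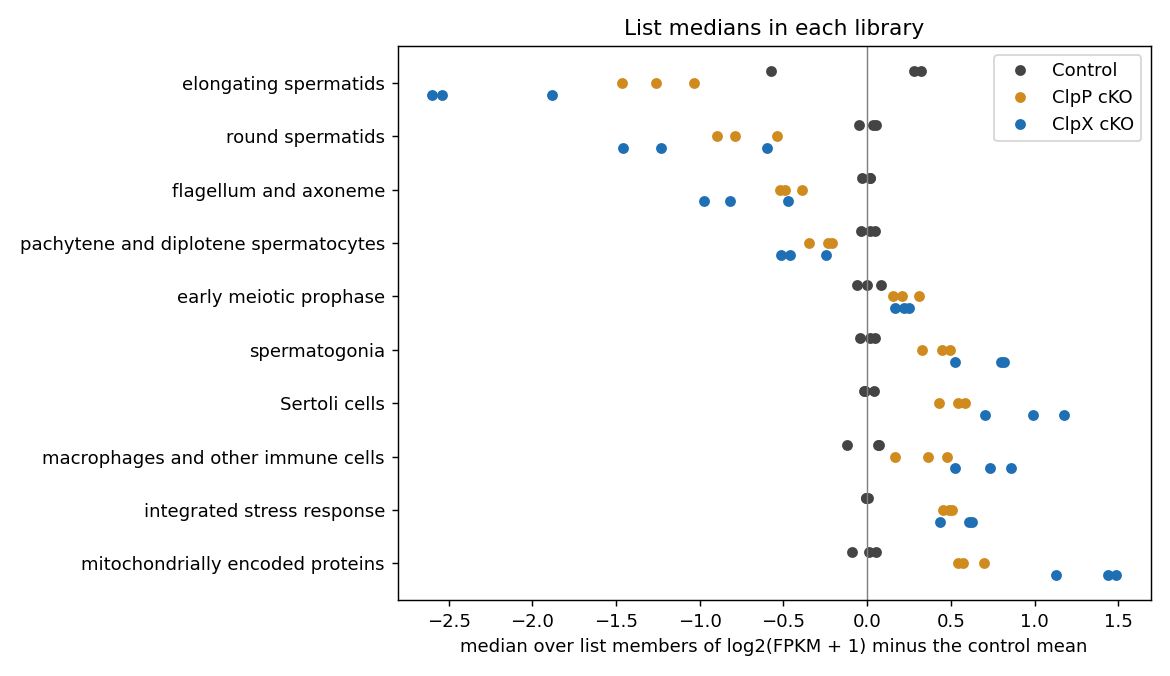
Median over the members of 10 gene lists (rows) of log2(FPKM + 1) minus the control mean (horizontal axis), 1 point per library, colored by group. Elongating spermatid genes lie at 0.28, 0.32 and -0.57 in the controls and from -2.60 to -1.88 in ClpX cKO, while Sertoli cell genes lie from 0.70 to 1.18 in ClpX cKO.

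All 13 mitochondrially encoded genes rose in ClpX cKO (13 adjusted over the list alone; median 1.39, SD over members 0.35; adjusted p = 0.52 with an estimated correlation). The share of reads from the mitochondrial chromosome was 2.69 ± 0.400%, and mt-Nd2 rose 3.06-fold (1.61, SE 0.10, adjusted p = 3.8e-04). Atp5e (ENSMUSG00000016252, chromosome 2, 174461072 to 174464105), the epsilon subunit of ATP synthase, fell by 2.19 (SE 0.21, adjusted p = 4.5e-04), from 37.8 ± 12.5 FPKM to 7.24 ± 0.850. Nuclear subunits went both ways. In ATP synthase 4 rose and 2, Atp5e included, fell of 15 (4 and 2 adjusted over the list alone; median 0.08), in complex I 7 rose and 6 fell of 35 (7 and 6; median 0.00, or 0.30 under quantile normalization), in complexes II and III 4 rose and 2 fell of 13 (4 and 2; median 0.12), and in complex IV with cytochrome c 6 rose and 6 fell of 18 (6 and 6; median -0.01, or 0.36 under quantile normalization). The ATP synthase median was 0.04 without Control 2, -0.005 without Control 3 and -0.004 without ClpX cKO 3. That of complexes II and III was 0.06 without ClpX cKO 3. Tfam fell by 1.72 (SE 0.20), while Mgme1, a nuclease of mitochondrial DNA, rose by 0.69 (SE 0.08). In their list of 16, 7 rose and 4 fell (7 and 4 adjusted over the list alone), and in ClpP cKO 7 rose and 3 fell (7 and 4). Chaperones and proteases rose in 7 of 16 cases and fell in 2 (7 and 2 adjusted over the list alone), with Hspd1 at 0.89 (SE 0.11) and Lonp1 at 0.80 (SE 0.09). Camera did not call the list of chaperones and proteases (adjusted p = 0.13), and 5138 of all 12827 tested protein-coding genes rose in ClpX cKO. In the same libraries Sertoli and elongating spermatid markers had medians of 0.96 and -2.33, and shares of cells were not tested as a cause here.

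**Figure D3:**
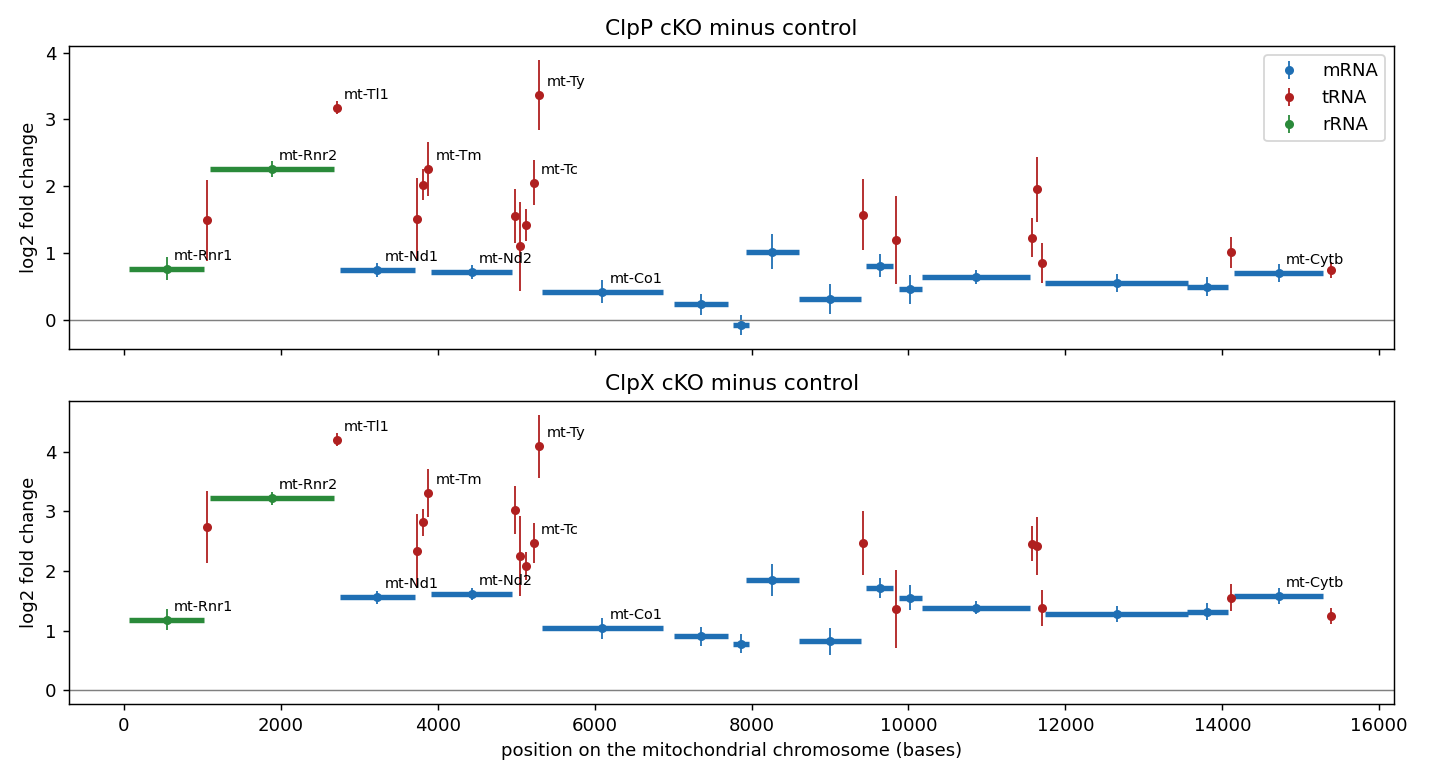
Log2 change against control (vertical axis, SE as error bars) of each tested mitochondrial gene by its position on the mitochondrial chromosome (horizontal axis, bases), in ClpP cKO and ClpX cKO (panels), with mRNA, tRNA and rRNA genes colored. In ClpX cKO the large rRNA mt-Rnr2 lies at 3.21 and mt-Tl1 at 4.20, above mt-Nd1 at 1.56 and mt-Nd2 at 1.61.

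Of 15 integrated stress response genes 10 rose and 2 fell in ClpX cKO (10 and 2 adjusted over the list alone; median 0.62; adjusted p = 0.52 with an estimated correlation), with Sesn2 at 0.92 (SE 0.11) and Atf4 at 0.72 (SE 0.09). The pair that fell was Asns (-0.90) and Ddit3 (-0.21), the asparagine synthetase and the factor CHOP, chosen after their values were seen. Of 32 mTORC1 pathway components 21 rose and 2 fell (22 and 2 adjusted over the list alone; median 0.41), among them Lamtor3 (0.76, SE 0.09) and Sesn1 (0.72, SE 0.08). Eif4e, the cap-binding factor downstream of mTORC1, and Nprl2, part of an inhibitor of the pathway, were those that fell, by 0.64 and 0.21, and both were chosen after their values were seen. Sesn1, which rose, also encodes an inhibitor, so the rise of the list does not give the direction of the pathway's activity. Of the 18 genes that mTORC1 induces 12 rose and 4 fell (12 and 4 adjusted over the list alone; median 0.40), such as Scd2, a fatty acid desaturase (0.88, SE 0.09). Camera called both lists (adjusted p = 0.52 for each with an estimated correlation), the latter not without ClpX cKO 1 or ClpX cKO 3. Sertoli, immune and stromal markers rose in the same libraries (medians 0.96, 0.77 and 0.68), and whether changed shares of cells account for the stress and mTORC1 changes was not tested here either. The p53 and apoptosis genes rose in 10 of 17 cases and fell in 2 (10 and 2 adjusted over the list alone; median 0.50; adjusted p = 0.52 with an estimated correlation), with Bax at 2.14-fold (adjusted p = 4.5e-04) and Cdkn1a at 0.87 (SE 0.11). In ClpP cKO 7 of them rose and 1 fell (7 and 1).

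Of 24 glycolysis genes 14 fell and 5 rose in ClpP cKO (14 and 5 adjusted over the list alone; median -0.44), and 15 fell and 6 rose in ClpX cKO (15 and 6; median -0.60). Pgk2, the sperm phosphoglycerate kinase, fell by 1.74 (SE 0.20) and Hk1, a hexokinase with sperm forms, by 1.86 (SE 0.22) in ClpX cKO, whereas Pfkl, the liver-type phosphofructokinase, rose by 0.61 (SE 0.10) in ClpP cKO. Of 18 fatty acid oxidation genes 4 rose and 1 fell in ClpP cKO (2 and 1), and 11 rose and 1 fell in ClpX cKO (11 and 1; median 0.48), with the carnitine transferase gene Cpt1a at 0.76 (SE 0.08). Of 18 citric acid cycle genes 6 rose and 2 fell in ClpP cKO (7 and 2), and 9 rose and 4 fell in ClpX cKO (9 and 4). Of 8 haem synthesis genes 2 rose in ClpP cKO (0 adjusted over the list alone) and 6 in ClpX cKO (6; median 0.46). Camera called glycolysis in ClpP cKO (adjusted p = 0.54 with an estimated correlation) and glycolysis, fatty acid oxidation and haem synthesis in ClpX cKO (adjusted p = 0.52 for each with an estimated correlation). The glycolysis call was lost without ClpP cKO 1 in ClpP cKO, and in ClpX cKO without any 1 of 7 libraries, all but Control 3 and ClpX cKO 3. Fatty acid oxidation was called in ClpP cKO without ClpX cKO 3. These metabolic genes were measured where Sertoli and elongating spermatid markers had medians of 0.54 and -1.25 in ClpP cKO and of 0.96 and -2.33 in ClpX cKO, and shares of cells were not tested as a cause.

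Of 526 X-linked genes 196 rose and 87 fell in ClpP cKO (205 and 95 adjusted over the list alone; median 0.28), and 326 rose and 114 fell in ClpX cKO (328 and 118; median 0.53), with the share of X-linked reads at 1.17 ± 0.042%, 1.42 ± 0.026% and 1.72 ± 0.183% in control, ClpP cKO and ClpX cKO. Of 9 Y-linked genes 3 rose in each knockout (3 and 3), including Ddx3y at 0.68 (SE 0.09) in ClpX cKO. Of 79 cytosolic ribosome genes 21 rose and 1 fell in ClpP cKO (14 and 1; median 0.22), and 47 rose and 1 fell in ClpX cKO (47 and 1; median 0.33), with Rpl10a at 0.92 (SE 0.12). Of 77 mitochondrial ribosome genes 17 rose and 5 fell (10 and 4; median 0.14), then 31 rose and 8 fell (26 and 8; median 0.18). For comparison, of all 12827 tested protein-coding genes 3306 rose in ClpP cKO and 5138 in ClpX cKO. Camera called the X-linked and both ribosome lists in both knockouts and the Y-linked list in ClpX cKO, none with an estimated correlation (adjusted p between 0.52 and 0.62). The mitochondrial ribosome call was lost without Control 3 in both, without ClpP cKO 2 in ClpP cKO, and without ClpX cKO 2 or 3 in ClpX cKO, and the Y-linked call without Control 1 or ClpX cKO 1. Sertoli markers (0.54 and 0.96) and elongating spermatid markers (-1.25 and -2.33) moved in the same libraries, and shares of cells were not tested as a cause of these changes either. The lists of fission and fusion (0 up and 4 down of 12, then 1 and 5; adjusted over the list alone 0 and 4, then 1 and 5), autophagy and mitophagy (4 and 7 of 17, then 9 and 8; 4 and 8, then 9 and 8), antioxidant defence (7 and 3 of 22, then 11 and 5; the same alone) and the piRNA pathway (8 and 4 of 17, then 6 and 6; the same alone) were not called. Cell division genes in ClpP cKO had 1 up and 7 down of 14 (1 and 7 alone), also without a call. In these, Mtfr1, a mitochondrial fission regulator, fell by 1.03 (SE 0.11), Gpx4, a peroxidase of lipid and sperm midpiece, by 1.07 (SE 0.14), Optn, a mitophagy receptor, by 0.63 (SE 0.07), and the piRNA factor Gtsf1 by 0.93 (SE 0.10) in ClpX cKO.

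The knockouts were compared for shared changes. Of the genes called in ClpP cKO, 94.9% were called in the same direction in ClpX cKO, 3344 up in both and 3985 down in both, where independent lists of these sizes would share 1148 and 1388. The total of 7329 was 4041 without Control 1, 4690 without Control 2, 3532 without ClpP cKO 2 and 3926 without ClpP cKO 3. Only Clpp was called in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated at 0.90, against 0.50 in simulated sets where the shared controls alone link the comparisons, and 90.9% had the same sign, against 66.7% simulated. In the simulated sets 0 genes were called in both on average. Genes were independent there, so these sets do not show what a control library that stands apart over many genes, such as Control 3, would add. Among genes lower in ClpP cKO, the ClpX cKO libraries lay lower again by a median of -0.24, and 86.9% were below 0. Among genes higher in ClpP cKO the median was 0.17, with 84.4% above 0. These genes were selected on the ClpP cKO values, and with 3 control libraries they could not be selected on separate controls.

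**Figure D4:**
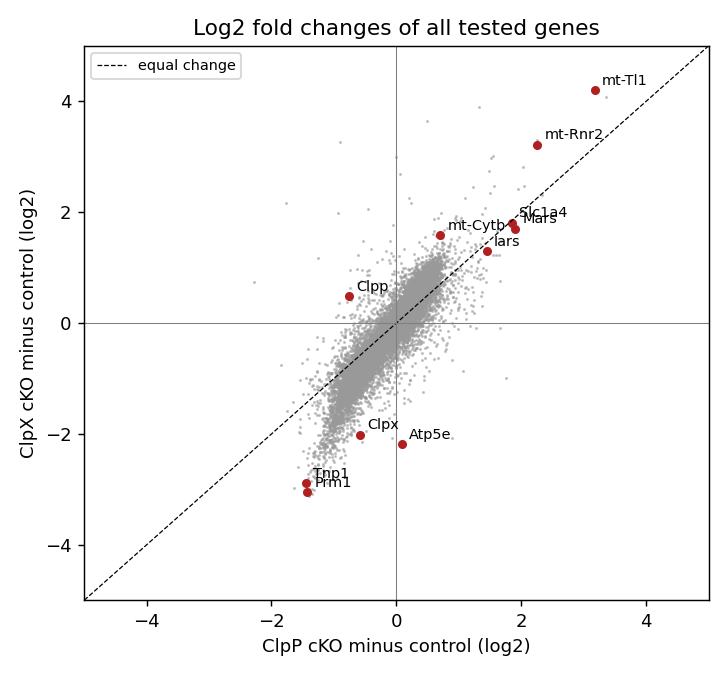
Log2 change against control of the 17266 tested genes (grey points) in ClpP cKO (horizontal axis) and ClpX cKO (vertical axis), with 11 genes in red and a dashed line of equal change. Prm1 lies at -1.43 and -3.05, below the dashed line, Mars at 1.90 and 1.70 close to it, and Clpp at -0.77 and 0.49 on opposite sides of 0.

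Compared directly, ClpX cKO had more of mt-Nd1 and mt-Nd2, which encode subunits of complex I, and less Atp5e than ClpP cKO. Atp5e was at 38.8 ± 2.43 FPKM in ClpP cKO and at 7.24 ± 0.850 in ClpX cKO (-2.28, SE 0.21, adjusted p = 0.015), Clpx was lower by -1.43 (SE 0.11, adjusted p = 0.0080), and Scgn, a calcium-binding protein gene, by -1.23 (SE 0.15, adjusted p = 0.034). Clpp (1.25, SE 0.14, adjusted p = 0.030), Scara3 (1.28, SE 0.17, adjusted p = 0.042), mt-Nd2 (0.90, SE 0.10, adjusted p = 0.030) and mt-Nd1 (0.82, SE 0.11, adjusted p = 0.039) were higher, the last 0.00 under quantile normalization. In all 8 genes were higher and 10 lower, and 4801 had an unadjusted p under 0.05. Libraries did not overlap for 29.9% of genes, where chance gives 10%. The total of 18 depended on single libraries: limma called 7 genes without Control 1, 8 without Control 2, 445 without Control 3, 3 without ClpP cKO 2, 4758 without ClpX cKO 1, 1 without ClpX cKO 2 and 6 without ClpX cKO 3. It called 0 without ClpP cKO 1 (3148 at an unadjusted p under 0.05) and 0 without ClpP cKO 3 (3677). Of the named genes, Clpx lost its call without ClpP cKO 1 or 3, and Atp5e without any 1 ClpP cKO library or without ClpX cKO 2 or 3. Scara3, mt-Nd1 and mt-Nd2 kept it only without Control 3 or ClpX cKO 1, Scgn also without ClpX cKO 3, and Clpp also without ClpP cKO 2. With no filter on low values 5 of the 8 genes that the rule names here lost their calls, among them Scara3, mt-Nd1, mt-Nd2 and Scgn. Without Control 3 and ClpX cKO 1, 5149 genes were called, which include all 18. With the replicate number as a block, 1 gene was called.

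As groups, elongating spermatid genes (19 of 19 lower adjusted over the list alone; median -1.11) and Sertoli cell genes (15 of 16 higher adjusted over the list alone; median 0.44) differed between the knockouts by a list test, although none of these genes was called over all genes. The 13 mitochondrially encoded genes were higher in ClpX cKO (2 over all genes, 13 adjusted over the list alone; median 0.83), and so were immune genes (0 over all genes, 6 higher and 1 lower adjusted over the list alone; median 0.42, or 0.27 without ClpX cKO 3), interferon-stimulated genes (0, and 5 adjusted over the list alone; median 0.47) and haem synthesis genes (0, and 5 adjusted over the list alone; median 0.27). Camera called these 6 lists and 12 more, none with an estimated correlation (adjusted p of at least 0.54). The integrated stress response genes had a median of 0.06 and were not called. Their median was 0.13 without ClpP cKO 2, 0.12 without ClpX cKO 1, -0.03 without ClpP cKO 1 and -0.02 without ClpX cKO 3.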

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

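No test in this part was chosen after its result was seen. Clpp stood out because its changes against control went in opposite directions in the knockouts, -0.77 in ClpP cKO and 0.49 in ClpX cKO (log2), and the direct difference passed its test (1.25, SE 0.14, adjusted p = 0.030, higher in 3 of 3 ClpX cKO libraries). The difference was between 1.09 and 1.39 when single libraries were left out, and it was not called without Control 1, Control 2, ClpP cKO 1, ClpP cKO 3, ClpX cKO 2 or ClpX cKO 3. Clpp is the gene targeted in ClpP cKO, so its fall there, which is part of the direct difference, follows from the design. No explanation of its rise in ClpX cKO was tested. With 3 libraries per group, no library was tested for lying apart within its group.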

How the results depend on the processing

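The tests with limma voom, with libraries scaled by their own totals and without Control 3 and ClpX cKO 1 were chosen only after the results were seen. In ClpP cKO against control, 2298 genes were higher at a mean FPKM of at least 5, and 5992 higher and 2404 lower with own totals. Without single libraries the counts ran from 1593 to 4108 higher and from 2024 to 4621 lower, and genes called in both knockouts from 3532 to 8298, lowest without ClpP cKO 2 and highest without ClpX cKO 1. In ClpX cKO against control, 3019 were higher at a mean FPKM of at least 5. The filter leaves fewer genes to test, and the cause of the others was not tested. In ClpX cKO against ClpP cKO, quantile normalization gave 18 lower, the 6 libraries alone 18 higher and 71 lower, protein-coding genes alone 6 lower, voom 23 higher, and the omission of Control 3 and ClpX cKO 1 gave 2177 higher and 2972 lower. Without single libraries the counts ran from 0 (without ClpP cKO 1 or 3) to 2060 higher and 2698 lower (without ClpX cKO 1). The cause was not tested. The labels do not say that the replicate numbers pair the libraries. Deviations from the group mean correlated across genes at 0.06, 0.06 and -0.07 between control and ClpP cKO libraries of 1 number. The correlations were 0.13, 0.05 and 0.19 between control and ClpX cKO, and 0.23, 0.17 and 0.02 between the knockouts. These values do not settle whether the libraries are paired. With the number as a block, 7845 and 11291 genes were called against control, and 0 higher and 1 lower between the knockouts, where 7 of 8 named genes lost their calls.

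Among named genes and lists that were called before or after, sign changes came from quantile normalization, except for the Y-linked list in ClpX cKO, which was at -0.044 with no filter. In ClpP cKO they were Ndufc1 (0.044), Uqcrfs1 (0.092), Cox7a2 (0.027), Cox5a (0.031), Cox7b2 (0.088), the pachytene list (0.010) and the list of complexes II and III (0.23). In ClpX cKO they were Uqcrc1 (0.19), Cox7b2 (0.090) and the complex IV list (0.36). The cause was not tested. Quantile normalization kept 6020 of the 7722 ClpP cKO calls and 10196 of the 11326 ClpX cKO calls, and own totals kept 5977 and 9813. Over all genes, 214 and 347 of these calls had the opposite sign under quantile normalization and 10 and 109 under own totals. Over all alternatives together the named genes kept direction and side of the threshold in 4840 cases, lost the call in 228 and changed sign in 7. At a mean FPKM of at least 5, 28 results for genes and 6 for lists had no value. Camera calls of lists also depended on the genes tested. With protein-coding genes only, 3 list calls were lost in ClpP cKO, 7 in ClpX cKO and 1 between the knockouts. At a mean FPKM of at least 5, 2, 6 and 3 were lost. With no filter 41170 genes were tested, of which 5466 and 12000 were called against control. Depth, 14334436 to 17021685 reads, was not varied.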

Other observations

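The lists of synthetases, amino acid transporters and mitochondrial and small nuclear RNA genes in this part, and the tests of the lower share of spermatids and of 1 factor for mitochondrial RNA, were chosen only after the results were seen. Most genes of the enzymes that load tRNAs with amino acids in the cytosol rose in both knockouts. Of 20 cytosolic aminoacyl-tRNA synthetase genes 13 rose and 1, Vars, fell in ClpP cKO (median 0.43, adjusted p = 8.8e-05, or adjusted p = 0.50 with an estimated correlation). In ClpX cKO 12 rose and 1 fell (median 0.36, adjusted p = 0.0065, or adjusted p = 0.49 with an estimated correlation). Mars was at 17.7, 68.8 and 60.6 FPKM, Iars at 12.1, 34.9 and 31.6 and Gars at 19.8, 50.6 and 44.0 in control, ClpP cKO and ClpX cKO. Vars fell by 0.72 (SE 0.16) and by 1.19 (SE 0.16). Of 17 mitochondrial synthetase genes 8 rose and 1 fell in ClpP cKO (median 0.28) and 10 rose and 3 fell in ClpX cKO (median 0.33). Of 8 amino acid transporter genes 6 rose in ClpP cKO (median 0.51) and 7 in ClpX cKO (median 0.71), among them Slc7a5 (0.52 and 0.79) and Slc3a2 (0.57 and 0.85), which together form a carrier of large neutral amino acids.

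On the mitochondrial chromosome, the median change of rRNA and tRNA genes was above that of the genes of proteins (0.55 in ClpP cKO and 1.39 in ClpX cKO). Of 19 rRNA and tRNA genes 15 rose in ClpP cKO (median 1.505, adjusted p = 2.5e-07, or adjusted p = 0.50 with an estimated correlation) and 18 in ClpX cKO (median 2.46, adjusted p = 3.0e-07, or adjusted p = 0.49 with an estimated correlation). With 3 tRNA genes that had no control read set at 3 reads per control library, the medians were 1.23 and 2.25. Other tRNA genes were low in the controls too, such as mt-Th (4.19 FPKM), mt-Tw (3.86), mt-Tg (1.40) and mt-Tm (0.35). On genes this short these are few reads, so the medians rest partly on genes near the floor. The large rRNA mt-Rnr2 was at 68.4 ± 5.79, 330.2 ± 23.1 and 645 ± 81.8 FPKM in control, ClpP cKO and ClpX cKO, and the small rRNA mt-Rnr1 at 54.3 ± 7.20, 92.8 ± 12.3 and 126 ± 26.1. In ClpX cKO mt-Rnr1 (1.19), mt-Tp (1.25), mt-Tr (1.37) and mt-Tl2 (1.38), chosen after their values were seen, lay below the median of the genes of proteins. The leucine tRNA mt-Tl1, which lies between mt-Rnr2 and mt-Nd1, was at 3.18 (SE 0.10) and 4.20 (SE 0.10). Of 234 small nucleolar and nuclear RNA genes 20 rose and 3 fell in ClpP cKO (median 0.20), and 23 rose and 18 fell in ClpX cKO (median 0.09). A stretch of chromosome 1 holds copies of mitochondrial genes, such as Gm10925 (0.96 and 1.85), and mt-Atp6 itself was at 1.02 and 1.85. Whether reads match both places was not tested.

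The fall of elongating spermatid genes was weighed first. The authors' scaling as the whole cause is argued against, since the list's median stayed at -0.83 (SD over members 0.26) in ClpP cKO and at -1.77 (SD 0.53) in ClpX cKO under the scaling that brought it nearest to 0. A lower share of spermatids alone would raise markers of all other cells alike, but Sertoli cell genes lay above pachytene and diplotene genes by 0.79 (SD between libraries 0.11, SD over the latter genes 0.32) in ClpP cKO and by 1.37 (SD 0.27 and 0.37) in ClpX cKO. This argues against it as far as those genes are not also transcribed in spermatids, which was not tested, and the difference from early prophase genes was beyond their spread in ClpX cKO (0.75, SD 0.42) and within it in ClpP cKO (0.30, SD 0.33). Changes in the shares of several cell types at once, and an effect of the knockouts within cells, may both contribute and stay open as untested.

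The excess of mitochondrial rRNA and tRNA over mitochondrial mRNA was weighed next. The difference of the medians per library, 0.96 (SD between libraries 0.10) in ClpP cKO and 1.11 (SD 0.16) in ClpX cKO, is the pattern itself and so tests no explanation, such as 1 factor for all mitochondrial RNA. Weaker selection of polyadenylated RNA stays open: the rRNA and tRNA genes stood above nuclear small RNA genes by 1.38 (SD 0.14) and 2.37 (SD 0.28), but this includes the rise of all mitochondrial genes, and the small RNA genes had a median of 3.89 reads per library. Several of the mitochondrial tRNA genes were near the floor in the controls as well. Reads that run from an rRNA or mRNA into a neighbouring tRNA gene, and the copies on chromosome 1, were not tested. An effect of the knockouts stays open as untested.

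The like rise of cytosolic synthetases in both knockouts was weighed last. Their median in ClpX cKO minus ClpP cKO was -0.08, with 0 of 20 genes called by limma, while that of Sertoli cell genes was 0.44. The synthetases thus lay below the Sertoli cell genes, at -0.49 (SD between libraries 0.11, SD over the synthetase genes 0.16). A lower share of spermatids alone would raise both lists further from ClpP cKO to ClpX cKO. The difference includes the pattern itself, so it does not decide whether such a lower share accounts for the synthetases. Whether the synthetase genes are also transcribed in spermatids was not tested. The synthetase list was chosen after its values were seen. An effect shared by both knockouts stays open as untested.

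Other splits of the 6 libraries were counted for each comparison, 10 splits each. The real split called 7722 genes in ClpP cKO against control, where the highest other called 3, and 1 split, the real one, reached its count. It called 11326 in ClpX cKO against control, where the highest other called 1, and 18 between the knockouts, where the highest other called 1. With 10 splits a share under 0.05 cannot be reached.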
